A study of Mus musculus with 8 samples.

How the data were processed

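H3K27ac, a histone acetylation found at active promoters and enhancers, was profiled in mouse colon cancer organoids by CUT&RUN, in which an antibody directs a nuclease to cut out and release the DNA bound to a chromatin mark. The 8 samples of the series comprise 3 libraries from Gata6 knockout AKP organoids, 3 from control AKP organoids, and 1 H3K4me3 and 1 IgG library from control organoids. The table analysed here holds the 6 H3K27ac libraries, and the H3K4me3 and IgG libraries were not analysed here, so no background level was subtracted.

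The authors deposited raw read counts per peak, with no normalization, over 1 peak set shared by the 6 libraries. Alignment was to mm9, and Bowtie, Picard, SAMtools, SEACR and bedtools were used, per the submitters' processing notes, which give neither versions nor roles. How the peaks of single libraries were combined, and which program counted the reads, are not given in the sources used here. The largest end on chromosome 1 was 196957781. Between 82.8% and 88.9% of the deposited counts in each library were even, as they would be if both mates of a read pair were counted, so counting error is wider than the number of reads implies. Positions are printed as the authors' table gives them. The table pairs peaks with no genes, and the gene table at hand describes another assembly (GRCm38.p6), so its coordinates were not laid over the peaks. It was used only for the number of protein-coding genes on each chromosome. Peaks are therefore named by position, the peaks at Gata6 itself were not analysed here, and the planned tests of gene lists, of promoters and of sequence motifs were not run.

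Each of the 22731 peaks passed edgeR's expression filter and was tested. The comparison used edgeR 4.0.16 in R 4.3.3: TMM factors, a quasi-likelihood fit with group as the only term, a two-sided test and Benjamini-Hochberg adjustment, with calls at an adjusted p under 0.05. Library size was the sum of reads in peaks, so levels are edgeR's CPM over reads in peaks, scaled by TMM, and a change shared by all peaks would not be seen. Standard errors of log2 fold changes were taken from the quasi-likelihood F statistic. The common dispersion corresponded to a coefficient of variation of 11.4% between libraries of a group, beyond the counting noise that the model assumes. On data simulated for this comparison over 22731 peaks, 55 of 100 peaks changed by 1.5-fold and 91 of 100 changed by 2-fold were recovered, with 13 calls among 22531 unchanged peaks. Only these 200 peaks were changed, while 21.8% of peaks were called in the real comparison. The adjusted p depends on the share of changed peaks, so recovery in the real comparison may differ.

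The labels do not say whether replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical. No 2 libraries looked like copies of one another: the chi-square per degree of freedom of halved counts was 1.53 to 1.84 within groups and 3.97 to 4.85 between them.

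Before the data were examined, the test, the definition of runs, the comparisons by chromosome and by width, the alternatives and the rule for named peaks were fixed. The rule took, per direction, the 12 called peaks with the largest absolute log2 fold change among those whose mean level reached the median of tested peaks and whose groups did not overlap; its limit of 1 peak per gene, and its parts on Gata6 and on gene lists, could not be applied without gene names. Runs were defined as 3 or more consecutive called peaks of one direction with gaps of at most 12.5 kb, and were compared with 100 random reassignments of the calls among peaks of the same count quintile. Correlations of fold change with width and with mean level across peaks were given as Spearman's rho from SciPy 1.17.1. Those between libraries were given as Pearson's r. The alternatives were DESeq2 1.42.0, other scaling factors, trended offsets (a loess fit over the mean count with a span of 0.3, set when the fit was written), other filters and thresholds, a replicate block, and each library left out in turn. For runs, the alternative was a gap of at most 25 kb. Fits without chromosome 5, with its shift removed, and on halved counts were added after the data had been seen. So were the exact two-sided permutation test of each chromosome's share of reads, the shares among reads off chromosome 5, the calls on it with its shift removed, the medians in 10-Mb windows, the counts of changes of at least 2-fold and the calls by width class.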

Results

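H3K27ac was compared between Gata6 knockout and control AKP colon cancer organoids, with 3 libraries per group, to ask which acetylated regions differ when GATA6, a transcription factor of the gut epithelium and other endodermal tissues, is lost. The level at Gata6 itself was not analysed here, so it did not check the labels. The 22731 peaks had a median width of 2690 bp and together covered 84.3 Mb of the mm9 genome. Reads in peaks numbered 5766379, 5141856 and 7026388 in control replicates 1 to 3 and 5738480, 5495414 and 6196455 in knockout replicates 1 to 3. The median peak held 144 to 196 reads per library. Log2 CPM across peaks correlated at 0.947 to 0.961 between libraries of a group and at 0.898 to 0.906 between libraries of different groups (Pearson's r across peaks, which are not independent replicates).

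Acetylation differed at 4960 peaks, or 21.8% of those tested. It was higher in the knockout at 2640 peaks and lower at 2320 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p under 0.05). The median log2 fold change was 0.66 among peaks called higher and -0.49 among peaks called lower. These medians cover called peaks only, and the calls differ in depth and place. The weakest 10% of peaks off chromosome 5, where only larger changes can be called, held 336 higher and 25 lower calls. Chromosome 5, with a median of -0.26 over all its peaks, held 27.2% of the lower calls. The medians are therefore no direct comparison of effect size. A change of at least 2-fold was seen at 572 higher peaks and at 92 lower peaks. The excess of strong gains narrowed when the scaling was allowed to vary with the mean count, to 396 higher and 126 lower peaks. In 2507 of the higher and 2124 of the lower peaks, the 3 libraries of one group lay entirely above the 3 of the other. Such separation was found at 33.8% of all peaks, against 10% by chance.

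The most strongly gained of the well-covered peaks lay on chromosomes 8, 4 and 2. The peak on chromosome 8 from 122845904 to 122849888 rose 3.90-fold, from 14.2 ± 1.93 CPM in control to 55.1 ± 10.9 CPM in knockout libraries (SD, n = 3 each), a log2 fold change of 1.96 ± 0.16 (SE). A peak on chromosome 4 from 53327719 to 53331348 rose 3.73-fold, from 18.3 ± 1.53 to 68.3 ± 3.19 CPM, and its neighbour from 53292026 to 53295073 rose 3.34-fold. The highest knockout level among these 12 peaks, 113 ± 7.39 CPM, was found on chromosome 2 from 59305584 to 59311146, where control libraries held 32.6 ± 3.92 CPM. The peak on chromosome 14 from 55780786 to 55784494 rose from 13.3 ± 1.27 to 44.5 ± 0.241 CPM. On chromosome 5, where most changes went the other way, the peak from 77110157 to 77113368 rose 3.32-fold. The remaining 6 lay on chromosome 4 from 119505600 to 119510941 (3.27-fold) and from 57813017 to 57815954 (3.04-fold), on chromosome 1 from 137694815 to 137698418 (3.21-fold), on chromosome 10 from 39206711 to 39211472 (3.15-fold), on chromosome 16 from 9148615 to 9150644 (3.05-fold) and on chromosome 13 from 73393532 to 73400184 (3.04-fold). The largest adjusted p of the 12 was 7.25e-22 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

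Among the well-covered peaks that lost acetylation, a pair of neighbours on chromosome 2 fell most. The peak from 165915453 to 165919446 fell from 44.4 ± 4.97 CPM in control to 15.4 ± 1.30 CPM in knockout libraries (SD, n = 3 each), a 2.88-fold loss with a log2 fold change of -1.53 ± 0.17 (SE). Its neighbour from 165910605 to 165913195 fell 2.78-fold. Another pair of neighbours on chromosome 12, from 112684963 to 112689031 and from 112665416 to 112671692, fell 2.69-fold and 2.29-fold, the latter from 154 ± 20.1 to 67.4 ± 6.51 CPM. The peak on chromosome 3 from 86953007 to 86958710 fell from 124 ± 12.1 to 47.6 ± 1.93 CPM. On chromosome 5, the peak from 66948837 to 66954767 fell from 114 ± 2.98 to 47.3 ± 0.474 CPM, and its log2 fold change was -1.01 after the shift of the whole chromosome had been removed (adjusted p = 7.27e-20, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Losses of 2.65-fold and 2.43-fold were measured on chromosome 16 from 43624113 to 43627195 and from 90884870 to 90887290. The other 4 fell 2.26-fold to 2.39-fold, on chromosome 8 from 97665346 to 97669111, on chromosome 14 from 122081737 to 122087165, on chromosome 9 from 27116924 to 27120267 and on chromosome 10 from 126601744 to 126605504. The largest adjusted p of the 12 losses was 6.90e-12 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

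**Figure D1:**
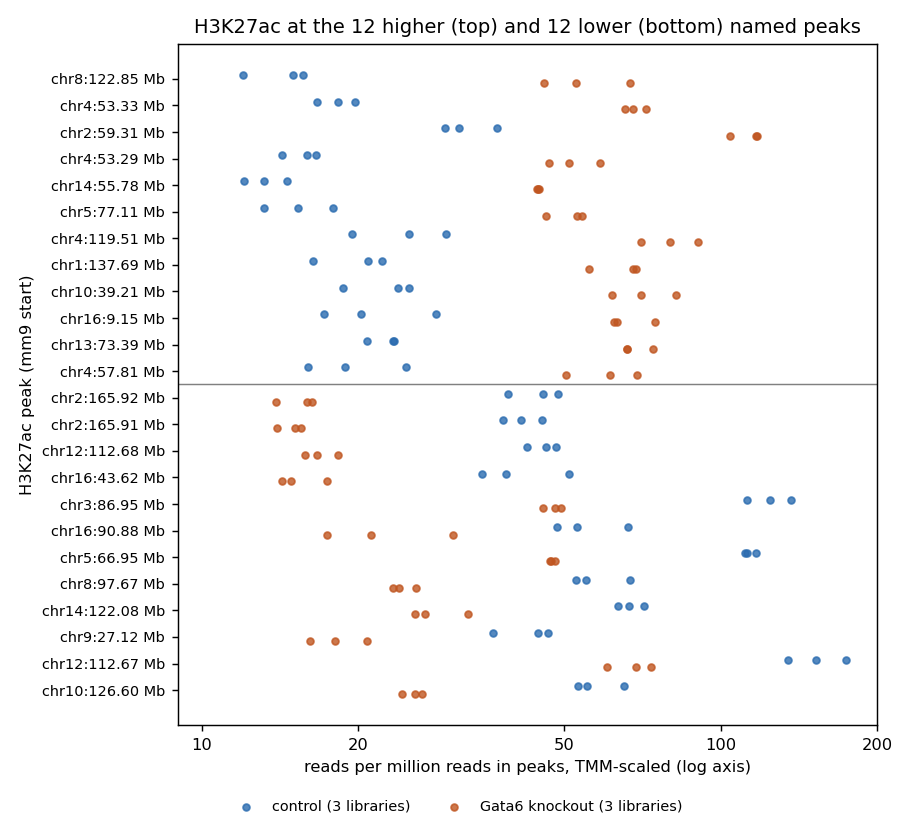
H3K27ac level in each library (x axis, CPM over reads in peaks, log scale) at the 12 higher and 12 lower named peaks (y axis, mm9 start), with 1 point per library, 3 control in blue and 3 Gata6 knockout in orange. The 3 libraries of one group lie apart from the 3 of the other at each of the 24 peaks, which was a condition of their choice.

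Part of the changed peaks lay next to one another. There were 120 runs of 3 or more adjacent peaks called higher, holding 462 of the 2640 higher peaks, and 100 runs called lower, holding 416 of the 2320 lower peaks. Random placement of the calls among peaks of similar count gave at most 22 higher and 20 lower runs in 100 reassignments. When calls were also kept on their chromosome, the highest numbers were 22 and 49, since lower calls were crowded on chromosome 5. The run with the most gained peaks lay on chromosome 19 from 47446645 to 47530329, where 12 adjacent peaks rose and their summed level went from 291 ± 9.10 to 590.1 ± 22.3 CPM (SD, n = 3 each), a 2.03-fold difference. With trended offsets, 10 of these 12 peaks were still called. A run of 8 peaks on chromosome 8 from 91044143 to 91116141 rose 1.71-fold, from 489 ± 17.5 to 837 ± 20.6 CPM. On chromosome 7, 8 adjacent peaks from 103669362 to 103733754 rose 1.67-fold and 8 from 136793805 to 136842149 rose 1.82-fold. The runs of 7 gained peaks lay on chromosome 8 from 122749192 to 122810652 (1.89-fold), on chromosome 4 from 148158960 to 148211247 (1.71-fold), on chromosome 10 from 39237090 to 39275776 (2.17-fold) and on chromosome 11 from 82640187 to 82676695 (1.89-fold).

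Of the 100 runs called lower, 47 lay on chromosome 5. The run with the most lost peaks lay on chromosome 1 from 62750547 to 62831426, where 10 adjacent peaks fell and their summed level went from 685 ± 11.8 to 456 ± 18.9 CPM (SD, n = 3 each). On chromosome 15, 7 peaks from 101146833 to 101221209 went from 811 ± 18.2 to 580.2 ± 31.0 CPM. The runs with the most peaks on chromosome 5 held 9 peaks from 140636985 to 140749468, whose sum went from 1672 ± 16.6 to 1083 ± 8.43 CPM, and 8 peaks from 66845030 to 66888375, whose sum went from 356 ± 24.0 to 193 ± 18.4 CPM. Another 4 runs on chromosome 5 held 7 peaks each, from 116303051 to 116366243, from 124633917 to 124690294, from 139879019 to 139930393 and from 24557257 to 24607992, and their knockout sums were 0.634 to 0.751 times the control sums. With the chromosome-wide shift removed there were 55 lower runs in place of 100, against at most 15 in reassignments within chromosome and count quintile. The sums given for runs on chromosome 5 include this shift. How many of its 47 runs remained without it was not counted here. The runs named here are those of at least 7 peaks in either direction, a limit set after the values were seen, and their sums are of peaks already called.

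**Figure D2:**
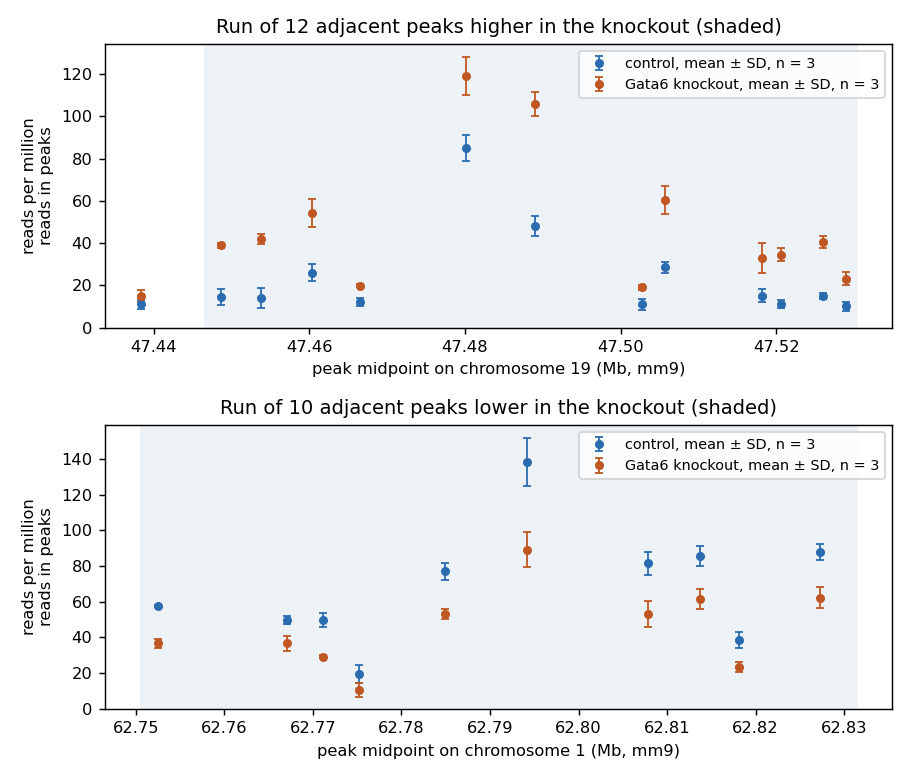
H3K27ac level of each peak (y axis, CPM over reads in peaks, mean ± SD of 3 libraries) by position (x axis, Mb in mm9) in the run with the most gained peaks, on chromosome 19, and the run with the most lost peaks, on chromosome 1, both shaded. Knockout means (orange) lie above control means (blue) at all 12 shaded peaks in the upper panel and below them at all 10 in the lower panel.

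Chromosome 5 stood apart from the other chromosomes. Its 1863 peaks had a median log2 fold change of -0.26, while the medians of the other 18 autosomes ranged from -0.03 to 0.05. Of its peaks, 630 were called lower and 83 higher, so that 33.8% were lower, against 4.56% to 12.2% on the other autosomes. Chromosome 5 held 8.20% of the peaks but 27.2% of the lower calls. With its median shift taken off, which centres its peaks near 0 by construction, 162 of its peaks were called lower and 212 higher. The share of all reads in peaks that fell on chromosome 5 was 10.3% ± 0.0845 in control and 8.79% ± 0.00713 in knockout libraries (SD, n = 3 each). An exact two-sided permutation test gave p = 0.1, the smallest that 3 libraries against 3 allow, so no chromosome could pass 0.05, before or after adjustment over the 20 compared. The groups lay apart, with this same smallest p, on 14 of the 20 chromosomes, so the test did not single out chromosome 5. The mean share fell by 14.8% of its control value on chromosome 5, which raises the shares of all others, since shares sum to 100%. Among reads off chromosome 5, the changes of the other 18 autosomes ranged from -3.78% of the control share on chromosome 12 to 2.54% on chromosome 6, and the share of X was 8.13% higher in the knockout. Off chromosome 5, 2557 peaks were called higher and 1690 lower in the fit to all peaks. When chromosome 5 was left out of the fit and its scaling, 2347 were called higher and 1857 lower. The excess of higher calls off chromosome 5 was therefore smaller without it and depended on the scaling.

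**Figure D3:**
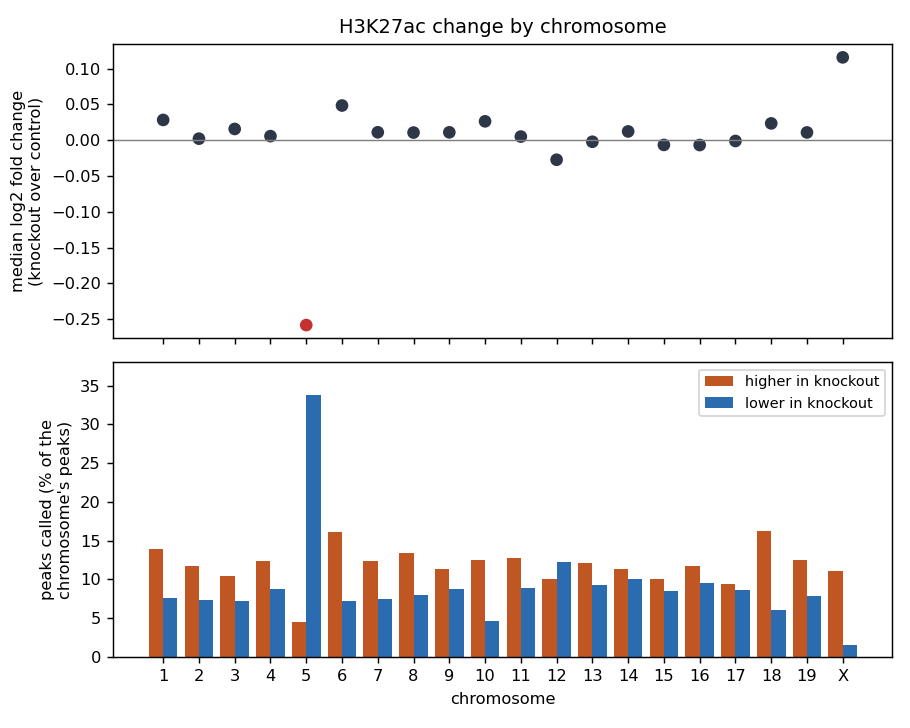
Median log2 fold change of all peaks on each chromosome (upper panel, knockout over control) and the percentage of the chromosome's peaks called higher (orange) or lower (blue) in the knockout (lower panel). Chromosome 5 has a median of -0.26 and 33.8% of its peaks called lower.

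The fall ran along the chromosome. In each of the 14 windows of 10 Mb that held at least 20 peaks, the chromosome 5 median lay below 0, between -0.51 and -0.10. The 217 such windows elsewhere ranged from -0.19 to 0.43, and 11 of the 14 windows lay below the lowest of them.

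**Figure D4:**
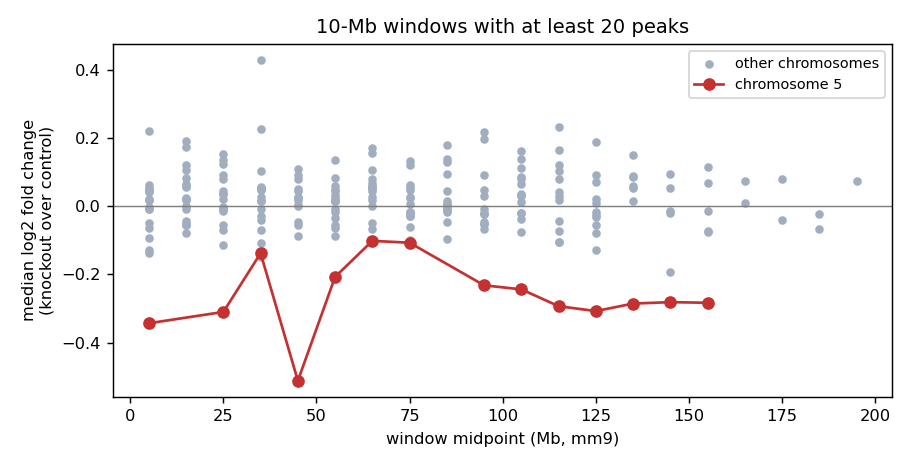
Median log2 fold change (y axis, knockout over control) of the peaks in each 10-Mb window with at least 20 peaks, by window midpoint (x axis, Mb in mm9), for chromosome 5 (red line) and all other chromosomes (grey points). The 14 windows of chromosome 5 all lie below 0, from -0.51 to -0.10.

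On chromosome X, 136 peaks were found, with a median log2 fold change of 0.12, 15 peaks called higher and 2 called lower. Their median level in control libraries, 19.7 CPM, was below that of each autosome, and weak peaks off chromosome 5 leaned towards gains as a class. Chromosomes 18 and 6 had the largest shares of higher calls, 16.3% and 16.1% of their peaks. Lower calls were more numerous than higher calls on chromosome 12, with 113 against 93, as well as on chromosome 5. On chromosome 10, 131 peaks were called higher and 48 lower.

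Under the TMM scaling, losses fell on wider peaks than gains. The median width was 3829 bp among peaks called lower, 2870 bp among peaks called higher and 2573 bp among those not called. Among the widest peaks, of 4641 to 100737 bp, 20.6% were called lower and 13.5% higher, and among the narrowest, of 106 to 1844 bp, 3.14% were called lower and 9.86% higher (the upper and lower 20% by width). Across peaks, the fold change fell with width (Spearman's rho = -0.139) and with mean level (rho = -0.165), although peaks are not independent replicates. These differences depended on the scaling. With trended offsets, which remove the trend with mean count, rho with width was 0.0346 and the median widths were 3448 bp for lower and 3166 bp for higher peaks. The widest class then held 753 lower and 754 higher peaks, in place of 936 and 615, and off chromosome 5 its 667 lower and 588 higher peaks became 515 and 724.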

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

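The fits on chromosome 5, halved counts and merged peaks, and the trended and chromosome 5 checks of peak width, were chosen after the data had been seen, as were the chromosome 5 medians other than with total counts or a library left out. Across DESeq2, DESeq2 size factors, total counts, upper-quartile factors, trended offsets, halved counts and both other filters (1 removed no peak and so tests nothing), higher peaks numbered 2640 to 2743 and lower peaks 2145 to 2340. DESeq2 shared 96.6% of the 4960 calls and trended offsets 88.6%. Leaving out each library in turn gave 2220 to 2367 higher and 1741 to 1996 lower peaks. The labels do not say whether same-numbered libraries were paired. Deviations of same-numbered libraries from the group means correlated at 0.00591 to 0.0668, against -0.0489 to 0.0403 for other pairs. Not every library correlated best with its own number. These values neither show nor exclude a weak pairing. With the number as a replicate block there were 2704 higher and 2409 lower peaks, and no named peak lost its call. At an adjusted p under 0.01 there were 1872 higher and 1478 lower peaks, and a test against a 1.5-fold change (glmTreat) left 381 higher and 85 lower, which moved the higher share of calls from 53.2% to 81.8%; fewer small changes can pass by construction. Without chromosome 5 there were 2347 higher and 1857 lower peaks, and with its shift removed 2724 and 1816. The chromosome 5 median was -0.24 to -0.26 in the fits that kept its shift. Runs called lower numbered 55 with that shift removed, and merging peaks at most 3 kb apart left 63 higher and 54 lower runs, since fewer units remain. The relation of fold change with width reversed with trended offsets, to rho = 0.0346, because these offsets remove the trend with mean count; it was -0.132 without chromosome 5. Other settings for gene lists, promoters and motifs were not run, since no mm9 annotation or sequence was used here. All 264 values of the 24 named peaks under 11 alternatives kept their direction and call, which their choice as strong calls with separate groups made likely. Of all 4960 calls, the fits that left out 1 library shared 76.6% to 79.9%. With this depth, spread and number of libraries, 55 of 100 simulated 1.5-fold changes were recovered when 200 of 22731 peaks were changed. The adjusted p also depends on that share, so recovery in the real comparison, with 21.8% of peaks called, may differ. Which of depth, spread, number of libraries and share of changed peaks sets the limit was not tested.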

Other observations

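The tests of chromosome 5, of weak peaks and of merged or reassigned runs, and the streaks and windows, were chosen after the results were seen, while the count over splits of the libraries was planned. Streaks of at least 8 consecutive called peaks, whatever the gaps between them, numbered 15 for higher and 7 for lower acetylation. Of the 7, 4 lay on chromosome 5, and with its shift removed 11 of 18, 6 of 13, 4 of 10 and 6 of 9 of their peaks were still called lower. The gained streak with the most peaks lay on chromosome 10 from 39089448 to 39347380, where 14 consecutive peaks rose by 0.28 to 1.71 on the log2 scale and their sum went from 421 ± 26.2 to 709.7 ± 19.4 CPM (SD, n = 3 each). Other gained streaks held 13 peaks on chromosome 8 from 90970134 to 91116141 (656 ± 6.84 to 1229 ± 29.0 CPM), 11 on chromosome 12 from 109602821 to 109785954 (288 ± 16.7 to 674 ± 32.3 CPM) and 11 on chromosome 18 from 75916259 to 76288747 (346 ± 6.06 to 589 ± 16.6 CPM). The highest median among gained streaks, 1.39, belonged to 8 peaks on chromosome 5 from 77086075 to 77192950. Their sum, the lowest among gained streaks in control libraries, went from 82.0 ± 7.71 to 231 ± 8.69 CPM. With trended offsets, 6 of these 8 peaks were still called. In the other gained streaks named here, 12 of 14 were still called on chromosome 10, 13 of 13 on chromosome 8, 9 of 11 on chromosome 12 and 9 of 11 on chromosome 18.

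The lost streak with the most peaks held 18 peaks on chromosome 5 from 66702813 to 67012228, with a median log2 fold change of -0.81. Off chromosome 5, 9 consecutive peaks on chromosome 3 from 145421197 to 145560409 had a median of -0.88, and 8 on chromosome 14 from 122015876 to 122163938 a median of -0.86. Among 10-Mb windows with at least 20 peaks, the one from 30 to 40 Mb on chromosome 10 had the highest median, 0.43 over 32 peaks, with 16 called higher.

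The fall across chromosome 5 is consistent with a difference in its copy number between the control and knockout organoids, a hypothesis found and tested on the same data. In 100% of its 14 windows of 10 Mb the median was below 0, from -0.51 to -0.10. Its shift against the other autosomes was -0.22 to -0.26 in each count quintile. The windows were uneven, however. Those from 30 to 40, 60 to 70 and 70 to 80 Mb had medians of -0.14, -0.10 and -0.11, within the -0.19 to 0.43 of windows elsewhere. The window from 40 to 50 Mb, with 29 peaks, had -0.51. An equal copy change along the chromosome would by itself shift all windows alike. The sign of the windows cannot separate a copy change from a broad change in acetylation. A few strongly reduced regions would leave the median over all chromosome 5 peaks, -0.26, within the range of the other autosomes, whose lowest was -0.03. Scaling that varies with count left the chromosome 5 median at -0.25. In control libraries the median level of its peaks, 33.2 CPM, exceeded the 24.7 to 29.7 CPM of the other autosomes, while the knockout median, 28.2 CPM, lay within their range in knockout libraries. An acetylation change along the whole chromosome, as an effect of the knockout without a copy change, was not tested and stays open, since no genomic DNA was analysed here, and steps from 4 copies to 3 or from 3 to 2 in every cell, with reads in proportion to copies, would give -0.42 or -0.58.

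Weak peaks leaned towards gains: off chromosome 5, the 2087 weakest peaks by mean level (10% of peaks) held 336 higher and 25 lower calls, against 340 and 410 among the 2087 strongest. With trended offsets the weakest class had 1.86 higher calls per lower call (175 and 94), close to the 1.53 to 1.84 of the other 10% classes, so a difference in scaling or background between the groups may account for much of the excess. These offsets centre each level by construction, so they cannot show whether weak sites truly gained. In the weakest class 73.1% of peaks had a fold change above 0, which would also follow if weak peaks had entered the peak set mainly from knockout libraries; the sources used here do not say from which libraries each peak was called, and this and the scaling explanation cannot be told apart here.

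Adjacent calls were more frequent than chance placement gave: 120 higher and 100 lower runs were seen, against at most 22 and 49 in 100 reassignments within chromosome and count quintile. Division of one region into several peaks by the peak caller was tested by merging peaks at most 3 kb apart, which left 63 higher and 54 lower runs, against at most 19 and 27 in reassignments. Chance placement does not account for all the runs. Splitting at gaps of at most 3 kb does not account for all of them either, although it may add to their number. Runs allow wider gaps than this merge closed, and no wider merge was run. Splitting of one region at wider gaps was therefore not tested and stays open as a source of the remaining runs. Coordinated change of neighbouring peaks in the knockout is another candidate explanation that no further test addressed.

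With 6 libraries there are 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 2640 higher and 2320 lower peaks by edgeR, and the highest count of the other 9 was 0, with 364 to 634 peaks at an unadjusted p under 0.05 against 7280. Each of the other 9 mixes control and knockout libraries on both sides. A real difference then widens the spread within each side, so few calls were likely in advance and these counts do not measure chance. In either direction 1 of the 10 splits, the real one, gave as many calls.

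Chromosome X carried few peaks for its genes: 136 peaks for 966 protein-coding genes counted in the GRCm38.p6 gene table, or 0.141 per gene, against 0.856 to 1.37 on autosomes other than chromosome 5 and 1.47 on chromosome 5.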
